A study of Mus musculus with 6 samples.

How the data were processed

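RNA from pancreatic islets of 6 mice aged 8 weeks, on a mixed SV129 and C57BL/6 background, was measured on 1-colour Affymetrix mouse expression arrays, 3 arrays from animals labelled knockout and 3 from littermate controls. Per the labels' protocols, islets were freed with collagenase and purified on a density gradient, and total RNA was amplified in a single round to biotin-labelled complementary RNA. RMA, a method that corrects background, normalizes quantiles across arrays and summarises the probes of a probe set, is named in the submitters' processing notes, without a version. The deposited values are log2 expression values per probe set, as the authors made them, and each array column carries the identifier of 1 sample. Per the series' design text each array is a different animal, so the spread between arrays includes the spread between animals. Scanner files were not used here, so probe-level detection calls and scan dates were not analysed.

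The value table held 45101 probe sets. The 64 control probe sets of the manufacturer were kept out of every comparison, which left 45037 probe sets. Gene names came from the platform annotation, in which 34945 of these probe sets had a single gene symbol, 932 had several and 9160 had no listed name. Of the single-symbol probe sets, 34741 were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6. The annotation names no assembly, so that table served for names and for which genes neighbour each other, and no coordinates are given. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the one with the highest mean over all 6 arrays stood for the gene, which gave 18193 genes.

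Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with group as the only term, two-sided), and p-values were adjusted over all 45037 probe sets by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as a call. The number of probe sets with an unadjusted p under 0.01 and a change of at least 1.5-fold was counted as a description. Differences are arrays labelled knockout minus control on the log2 scale, with limma's moderated standard error. Group values are means ± SD of 3 arrays. RMA values carry no detection call, so a fold against a dim control level is open to the background level, and the percentile of the control mean among all probe sets is given where that matters.

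Before the data were examined, 28 gene lists were fixed, 7 of them as the main lists (PPAR target genes, fatty acid oxidation, beta cell identity, regulated exocytosis, Golgi and vesicle trafficking, actin cytoskeleton, proliferation). The other lists were lactogen- and growth-hormone-responsive islet genes, PPAR partner receptors and coregulators, diacylglycerol and protein kinase C or D signalling, oxidative phosphorylation, glycolysis, sterol and fatty acid synthesis, the unfolded protein response, the immediate early response, heat shock, the interferon response, sex-linked genes, and markers of alpha cells, of delta, PP and epsilon cells, and of acinar, duct, fibroblast (with stellate and smooth muscle), endothelial, immune, adipocyte, Schwann (with neuronal) and erythrocyte lineages. Of 799 list entries, 70 had no probe set named for them alone here. All lists but the sex-linked one, 27 in all, were tested with camera (limma) at a preset correlation of 0.01 between genes, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were counted with p adjusted over all probe sets and with p adjusted over the list alone. Lists overlap in part: 9 genes are shared by the PPAR target and fatty acid oxidation lists, and Ehhadh is also in the lactogen list.

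The rule for named genes was fixed before the data were examined. It took Ppard, Ppara, Pparg and the islet hormone genes, the 12 largest rises and the 12 largest falls among genes past adjusted p 0.05 whose groups did not overlap (names that are only clone identifiers were passed over), the 4 members with the smallest p of each main list, and the 2 with the smallest p of each other list. Genes named outside this rule are marked as chosen after their values were seen.

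The fit was tested on 20 simulated data sets with the 45037 probe sets at their measured means and spread, each with 200 probe sets changed at known folds. In these simulations of knockout against control, 87.7% of probe sets changed 4-fold were called, 34.2% of those changed 2-fold and 0.746% of those changed 1.5-fold, and 4.79% of calls were false. A list of genes each shifted up 2-fold was called in 20 of 20 data sets, and 0 of 400 unshifted lists were called. Smaller shifts of a list were not simulated. The simulated genes varied independently of each other, so these list results say little about lists whose genes vary together. In the 9 other splits of the real arrays camera called 3 to 8 of 27 lists. Those splits mix the groups and keep part of their difference, so these are not a count of false calls. The number of arrays limits the precision: changes under 2-fold were mostly out of reach of a call.

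The alternatives fixed beforehand were the replicate number as a block, an intensity trend and robust prior in eBayes, quantile normalization of the deposited values again, median centring, 2 filters on dim probe sets (a mean above the median probe set, or a log2 value above 6 on at least 3 arrays), array weights, leaving out each array in turn, the mean over all probe sets of a gene, the estimated correlation and fry. A covariate for acinar RNA, and leaving out the 2 control arrays with the most acinar RNA, were chosen after seeing the data. The latter fit has 1 control array left, so its spread comes from the arrays labelled knockout. Figures were drawn with matplotlib 3.10.9.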

Results

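The arrays compared islets of Langerhans from mice labelled as carrying a pancreatic deletion of Ppard and from their littermates. Ppard encodes PPARβ (also written PPARδ), a nuclear receptor activated by fatty acids that controls genes of lipid handling. Per the labels the deletion was made by crossing floxed Ppard alleles to a Cre recombinase driven by the Pdx1 promoter, which is active throughout the developing pancreas. Control littermates carried the floxed alleles without Cre. The comparison asks which islet transcripts differ between Cre-positive mice with floxed Ppard alleles and Cre-negative littermates. There were 0 arrays from Cre-positive mice with intact Ppard alleles. For every difference below, the deletion and the Cre transgene therefore cannot be told apart as its origin. The labels call the material beta-cells, while the protocol describes whole islets, which also hold alpha, delta and PP cells, vessels and immune cells. There were 3 arrays per group, each from a different mouse aged 8 weeks. The median log2 value per array lay between 5.39 and 5.49. Arrays labelled knockout correlated with each other at r between 0.991 and 0.993 over probe sets, control arrays at 0.981 to 0.991, and pairs across groups at 0.978 to 0.987.

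The targeted gene was not lower in the arrays labelled knockout. On its brighter probe set, Ppard had log2 values of 7.75, 7.56 and 7.12 in controls 1 to 3 and 8.01, 8.20 and 7.70 in the arrays labelled knockout 1 to 3 (7.48 ± 0.32 against 7.97 ± 0.25, SD, n = 3 each). The difference of 0.49 ± 0.20 (SE) did not pass the test (adjusted p = 0.377), and was 0.31 without control 3 and 0.63 without control 1. The other Ppard probe set differed by 0.35 ± 0.11 (adjusted p = 0.255). The labels state no deleted exon, and a probe set outside the deleted part checks nothing about the deletion, so the genotype rests on the labels. The related receptor genes Ppara (-0.28 ± 0.14, adjusted p = 0.472) and Pparg (-0.043 ± 0.097, adjusted p = 0.899, and 0.010 after median centring) did not pass either.

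Large rises dominated the comparison. Cldn8, which encodes a tight-junction claudin, went from 2.15 ± 0.15 in controls to 10.46 ± 0.18 in the arrays labelled knockout (SD, n = 3), a difference of 8.32 ± 0.14 (SE) or 319-fold (adjusted p = 4.67e-06). Dnah8, an axonemal dynein heavy chain, rose by 6.24 ± 0.58 (adjusted p = 0.00636), while its second probe set, with a similar control level, differed by 0.37 (adjusted p = 0.457). Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, rose from 3.85 ± 0.17 to 9.36 ± 0.76, which is 45.4-fold (adjusted p = 0.00179). Fbxw24 rose by 4.81 ± 0.21, the synaptotagmin gene Syt10 rose 24.2-fold, and Sftpd, which encodes the surfactant lectin SP-D, rose by 4.38 ± 0.17. Tmem47 (4.25 ± 0.36), the inward rectifier potassium channel gene Kcnj5 (4.14 ± 0.33), the TGF-beta family ligand Gdf3 (3.99 ± 0.26), the chloride channel gene Cftr (3.92 ± 0.21), Crispld2 (3.77 ± 0.54) and the small GTPase gene Rerg (3.61 ± 0.26) completed the 12 largest rises. A dimmer Kcnj5 probe set differed by 1.06 and did not pass (adjusted p = 0.218). Control levels of most of these genes were dim: the control mean of Cldn8 lay at percentile 3.6 of all probe sets and that of Tph1 at 28.9, so the folds depend on the background of the arrays. In contrast, Sftpd stood at percentile 60.0 in controls and reached 95.8. Leaving out any 1 of the 6 arrays kept 11 of these 12 genes past adjusted p 0.05. The exception was Crispld2, whose adjusted p reached 0.142.

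The falls were smaller. Mlph, which encodes the RAB27A effector melanophilin, fell by 2.35 on the log2 scale (SE 0.27, adjusted p = 0.0149), from 6.39 ± 0.51 to 4.04 ± 0.29. Dapl1 fell by 2.08 (SE 0.25, adjusted p = 0.0167), and Fxyd3, a regulator of the sodium pump, fell by 1.83 (SE 0.17, adjusted p = 0.00605). The small heat shock protein gene Hspb8 and the aminopeptidase N gene Anpep differed by -1.81 ± 0.19 and -1.81 ± 0.25. Emid1 (-1.76 ± 0.25), Nt5dc2 (-1.74 ± 0.18) and the voltage-gated potassium channel gene Kcnh1 (-1.72 ± 0.24) followed. Mlxipl, which encodes the glucose-responsive transcription factor ChREBP, fell by 1.69 (SE 0.20, adjusted p = 0.0177) from 7.89 ± 0.41. The tyrosine aminotransferase gene Tat (-1.55 ± 0.20), Pappa2 (-1.55 ± 0.15), a protease of IGF-binding proteins, and Reln (-1.52 ± 0.20) closed the list of 12. A second, dim probe set of Reln differed by 0.014. Of these 12, only Fxyd3 and Pappa2 stayed past adjusted p 0.05 whichever array was left out. For the other 10 the highest adjusted p in those fits lay between 0.0549 and 0.142. With the acinar covariate 11 of the 12 rises and 4 of the 12 falls passed. Crispld2, the rise that did not pass, differed by 4.29 ± 0.69 (SE). Without controls 2 and 3 the 12 rises differed by 3.52 (Tmem47) to 8.15 (Cldn8). The 12 falls then differed by -1.17 (Reln) to -2.30 (Emid1). Among the 8 falls that did not pass with the covariate, Reln differed by -1.28 ± 0.23 (SE) and Fxyd3 by -1.63 ± 0.20, both smaller than without it. Dapl1 (-2.07 ± 0.35) was of about the same size, and Emid1 (-2.15 ± 0.26), Anpep (-2.02 ± 0.32), Hspb8 (-1.94 ± 0.26), Kcnh1 (-1.78 ± 0.34) and Tat (-1.71 ± 0.26) were larger.

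**Figure D1:**
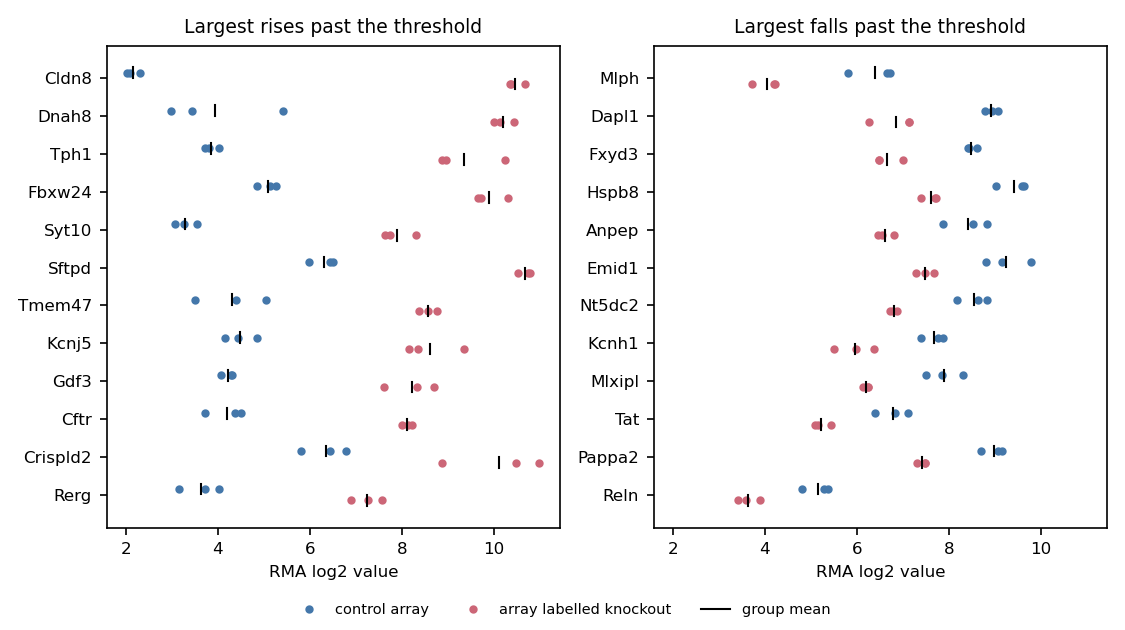
RMA log2 values of the 12 largest rises (left) and the 12 largest falls (right) past adjusted p 0.05, 1 point per array, with the group mean as a bar. In each gene all 3 arrays labelled knockout lie on 1 side of the 3 control arrays, and Cldn8 moves from 2.15 to 10.46.

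In total 404 of 45037 probe sets passed adjusted p 0.05, 321 higher and 83 lower in the arrays labelled knockout. On 1 probe set per gene, 155 genes rose and 45 fell. Of these, 59 rose by more than 4-fold and 2 fell by more than 4-fold. Counting every probe set with a single symbol, 254 genes had at least 1 call. In all 404 called probe sets the groups did not overlap, which a call with 3 arrays against 3 nearly ensures. Over all probe sets 19.0% did not overlap, and chance gives 10%. At an unadjusted p under 0.01 with at least 1.5-fold change there were 1463 probe sets, and chance alone gives about 450 at that p before any fold is asked for. The count of calls moved with single arrays: it was 783 without control 1, 239 without control 2, 152 without control 3, 161 without knockout 1, 161 without knockout 2 and 209 without knockout 3. With the acinar marker level of each array as a covariate it was 138, and 54 without controls 2 and 3, the arrays with the most acinar RNA (both chosen after seeing the data). The latter fit keeps a single control array, control 1, which is assumed to vary as the arrays labelled knockout do.

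**Figure D2:**
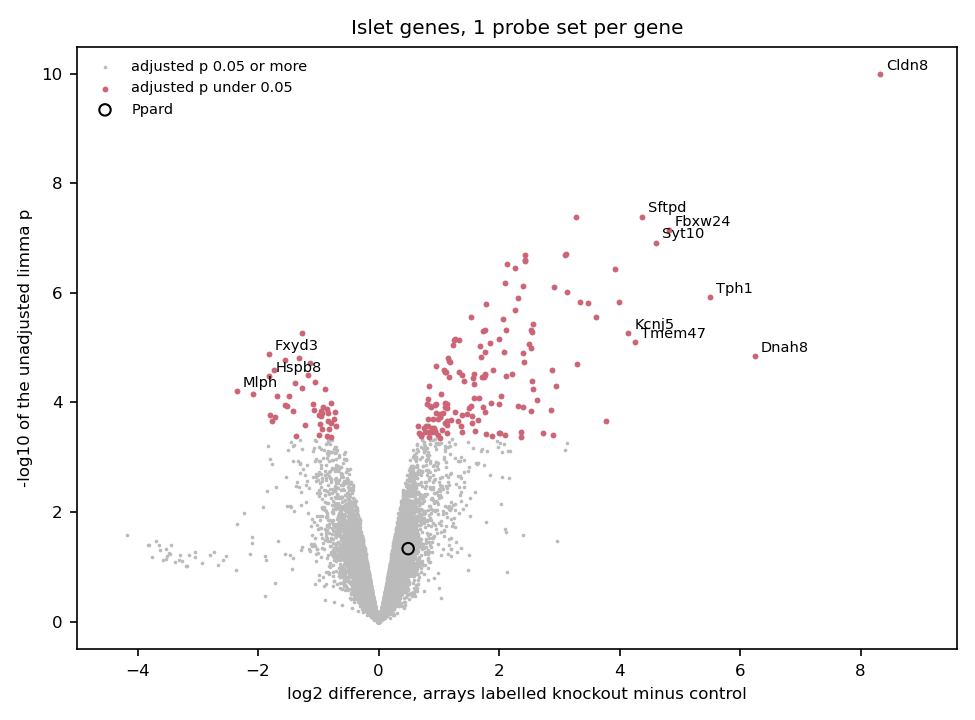
Log2 difference (arrays labelled knockout minus control, x axis) against -log10 of the unadjusted limma p (y axis) for 18193 genes, 1 probe set each. Genes past adjusted p 0.05 are red, and Ppard (circle) lies among the genes that did not pass.

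Of 27 gene lists tested, 11 passed adjusted p 0.05 with camera's preset correlation, 7 higher and 4 lower. None passed with an estimated correlation between genes (camera, lowest adjusted p = 0.108, 3 lists under an unadjusted 0.05), while 9 passed with fry, which asks whether a list moves on balance and does not set it against other genes. Of these 9, 5 were among the 11, and the others were proliferation (fry adjusted p = 0.0312), erythrocyte markers (0.0375), heat shock (0.0418) and actin cytoskeleton (0.0418). The list calls with camera therefore hold with the preset correlation only, and the p with an estimated correlation stands beside each.

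Genes that respond to lactogens and growth hormone in islets had the largest rise of the lists tested. On the brightest probe set of each gene, 5 of 9 rose (Tph1, Socs2, Matn2, Ehhadh and Cish), 0 fell and 4 did not pass. When adjusted over the list alone, 7 rose. A dimmer probe set of Ivd, 1 of those 4, rose by 1.17 ± 0.17 (SE, adjusted p = 0.0368, chosen after its values were seen). Socs2 and Cish, feedback inhibitors induced by cytokine receptor signalling through STAT5, rose by 2.09 ± 0.12 and 1.24 ± 0.11 (SE), and Cish, like Tph2, was chosen after its values were seen. The matrix protein gene Matn2 rose by 3.13 ± 0.19, from 7.32 ± 0.35 to 10.45 ± 0.17. Tph2, the neuronal counterpart of Tph1, differed by 1.70 ± 0.30 (adjusted p = 0.0631). The list mean was 6.92 ± 0.05 in controls and 8.87 ± 0.18 in the arrays labelled knockout (SD, n = 3), a difference of 1.95 ± 0.54 (SE over members). Camera gave an adjusted p of 2.12e-12 with the preset correlation, against an adjusted p = 0.108 with an estimated correlation.

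Markers of the other endocrine cells were lower. All 8 measured delta, PP and epsilon cell markers had lower means, 2 fell, 6 did not pass, and 7 fell when adjusted over the list alone. The ghrelin receptor gene Ghsr fell by 1.17 (SE 0.12, adjusted p = 0.0097) and Rbp4 fell by 0.73 (SE 0.10, adjusted p = 0.0265). With 1 array left out the adjusted p reached 0.0604 for Ghsr and 0.127 for Rbp4. The hormone genes Sst (-0.51 ± 0.12, adjusted p = 0.152) and Ppy (-0.34 ± 0.11, adjusted p = 0.282) did not pass. The list mean differed by -0.60 ± 0.12 (adjusted p = 5.81e-08, and adjusted p = 0.267 with an estimated correlation). All 8 alpha cell markers were lower, none passed over all probe sets, and 6 fell when adjusted over the list alone. The smallest p were those of the transcription factor gene Irx2 (-0.71 ± 0.12, adjusted p = 0.0593) and of Fap (-1.30 ± 0.25, adjusted p = 0.0846), while the glucagon gene Gcg differed by -0.16 ± 0.10 (adjusted p = 0.539). The alpha list mean differed by -0.54 ± 0.13 (adjusted p = 1.26e-06, and adjusted p = 0.154 with an estimated correlation). Gcg, Sst and Ppy lie near the top of the array's range, where differences are compressed. The acinar marker mean also differed between these groups, by -2.83.

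The beta cell identity list was slightly lower, by -0.18 ± 0.07 (adjusted p = 0.0264, and adjusted p = 0.607 with an estimated correlation). Of 24 members measured, 0 rose, 1 fell and 23 did not pass, with the same single fall when adjusted over the list alone. That gene was Slc30a8, the zinc transporter of insulin granules, which fell by 0.82 (SE 0.12, adjusted p = 0.0394). That call was kept in 1 of the 6 fits that left out 1 array (adjusted p up to 0.175). The prohormone convertase gene Pcsk1 differed by 0.54 ± 0.13 (adjusted p = 0.152), the carboxypeptidase gene Cpe by -0.31 ± 0.10 (adjusted p = 0.255) and Ucn3, a marker of mature beta cells, by -0.95 ± 0.33 (adjusted p = 0.305). Ins2 stood at 13.85 ± 0.02 in controls and 13.80 ± 0.08 in the arrays labelled knockout, at the top of the range (adjusted p = 0.887), and its difference was 0.0034 after median centring. The call on the list ended without control 1 (-0.086, adjusted p = 0.235) and without knockout 1 (-0.16, adjusted p = 0.0554). The difference was -0.27 without control 2 (adjusted p = 0.00125), -0.32 with the acinar covariate (adjusted p = 8.33e-04) and -0.36 against control 1 alone (adjusted p = 7.93e-04).

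Acinar markers, the digestive enzyme genes of the exocrine pancreas, varied between arrays rather than only between groups. Their mean over 34 genes was 6.27, 10.41 and 10.57 in controls 1 to 3 and 7.90, 5.36 and 5.51 in the arrays labelled knockout 1 to 3. The group means of 9.08 ± 2.44 and 6.26 ± 1.42 (SD, n = 3) overlapped (exact permutation p = 0.2, two-sided, where 3 against 3 cannot go under 0.1). No member passed over all probe sets or when adjusted over the list alone, and Amy1 (-2.35 ± 0.75, adjusted p = 0.259) and Reg3g (-1.11 ± 0.39, adjusted p = 0.312) had the smallest p. Camera called the list at adjusted p = 8.2e-10, against an adjusted p = 0.577 with an estimated correlation. Against control 1 alone, with controls 2 and 3 left out because of these same values, the difference was -0.0096 (adjusted p = 0.558).

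Genes of the unfolded protein response were higher as a group, by 0.33 ± 0.05 (adjusted p = 1.36e-11, and adjusted p = 0.374 with an estimated correlation). Of 34 measured, 32 had higher means. None passed over all probe sets, and 17 rose and 1 fell when adjusted over the list alone. Edem1, which helps clear misfolded glycoproteins, differed by 0.57 ± 0.11 (adjusted p = 0.0943) and the transcription factor gene Xbp1 by 0.63 ± 0.13 (adjusted p = 0.0985). Golgi and vesicle trafficking genes were higher by 0.10 ± 0.02 (adjusted p = 0.00515, and adjusted p = 0.577 with an estimated correlation), with 53 of 68 members higher and none past the threshold over all probe sets or over the list alone. Its members with the smallest p were the COPII coat gene Sec23b (0.43 ± 0.10), Arfgap3 (0.47 ± 0.12), Golga1 (0.32 ± 0.10, with a dimmer probe set at -0.22) and the COPI subunit gene Copz1 (0.32 ± 0.11), with adjusted p between 0.145 and 0.288. The Golgi call ended without knockout 2 (0.067, adjusted p = 0.106), after quantile normalization again (0.063, adjusted p = 0.0751), above the log2 floor (adjusted p = 0.0621) and with the acinar covariate (0.068, adjusted p = 0.0786). Glycolysis genes were higher by 0.20 ± 0.09 (adjusted p = 0.0256, and adjusted p = 0.363 with an estimated correlation). Of 17, only the phosphofructokinase gene Pfkp rose, by 1.07 ± 0.14 (adjusted p = 0.0266), also when adjusted over the list alone (adjusted p up to 0.129 with 1 array left out), and the glucose transporter gene Slc2a1 differed by 0.74 ± 0.22 (adjusted p = 0.233). The glycolysis call ended without control 1 (adjusted p = 0.113), without knockout 2 (adjusted p = 0.0511) and above the log2 floor (adjusted p = 0.0785).

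**Figure D3:**
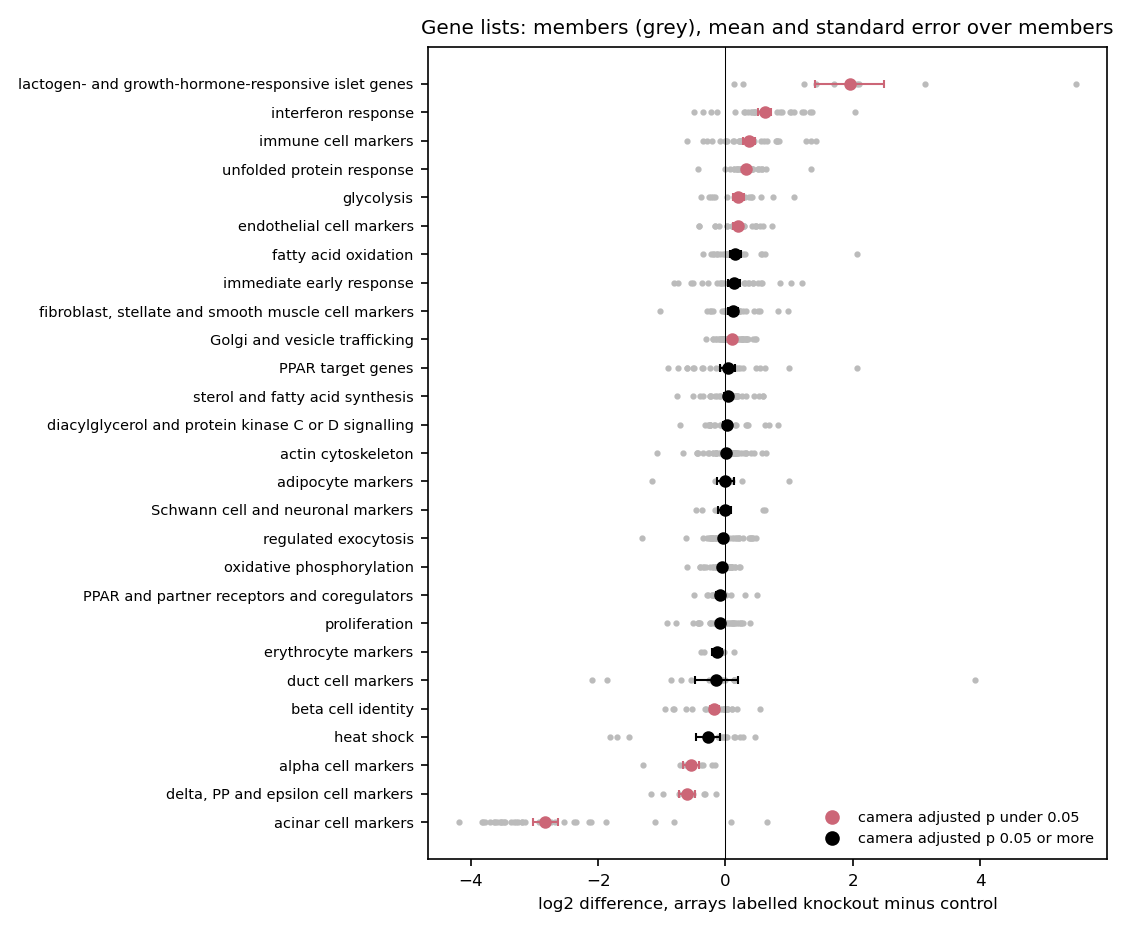
Log2 differences (arrays labelled knockout minus control) of the members of 27 gene lists (grey points) with the list mean and its standard error over members. Red means passed adjusted p 0.05 with camera's preset correlation, from 1.95 for the lactogen and growth hormone list to -2.83 for acinar markers.

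Immune and interferon genes were higher. Of 29 immune cell markers 1 rose, 0 fell and 28 did not pass, and 5 rose when adjusted over the list alone. Laptm5, a lysosomal membrane protein gene of blood cells, rose by 1.34 ± 0.11 (adjusted p = 0.00425) on its brightest probe set, while 1 of its 5 probe sets differed by -0.041. Tyrobp, an adaptor of myeloid receptors, differed by 0.65 ± 0.13 (adjusted p = 0.102). The immune list mean differed by 0.37 ± 0.09 (adjusted p = 2.24e-04, and adjusted p = 0.511 with an estimated correlation). Of 29 interferon response genes, the guanylate-binding protein gene Gbp6 rose by 1.01 ± 0.14 (adjusted p = 0.0279, and up to 0.133 with 1 array left out), 28 did not pass, and 7 rose when adjusted over the list alone. The chemokine gene Cxcl10 differed by 1.32 ± 0.28 (adjusted p = 0.107). The interferon list mean was 8.19, 7.37 and 7.58 in controls 1 to 3 and 8.54, 8.04 and 8.40 in the arrays labelled knockout 1 to 3, so control 1 stood above knockout 2. Its difference of 0.61 ± 0.10 (adjusted p = 2.67e-07, and adjusted p = 0.577 with an estimated correlation) was 0.36 with the acinar covariate (adjusted p = 0.00432). Against control 1 alone, which has the highest control mean, it was 0.14 and the call was lost (adjusted p = 0.262). Endothelial markers were higher by 0.19 ± 0.07 (adjusted p = 0.0431, and adjusted p = 0.713 with an estimated correlation), with no member past the threshold over all probe sets or over the list alone. Ptprb differed by 0.72 ± 0.22 and Gpihbp1, the capillary anchor of lipoprotein lipase, by 0.58 ± 0.18 (adjusted p = 0.235 and 0.247). The endothelial call ended in 10 of 16 alternatives, among them without control 2 (0.017, adjusted p = 0.634), control 3 (adjusted p = 0.0595) or knockout 2 (adjusted p = 0.15). The endothelial mean turned to -0.066 with the acinar covariate and was 0.35 without control 1.

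**Figure D4:**
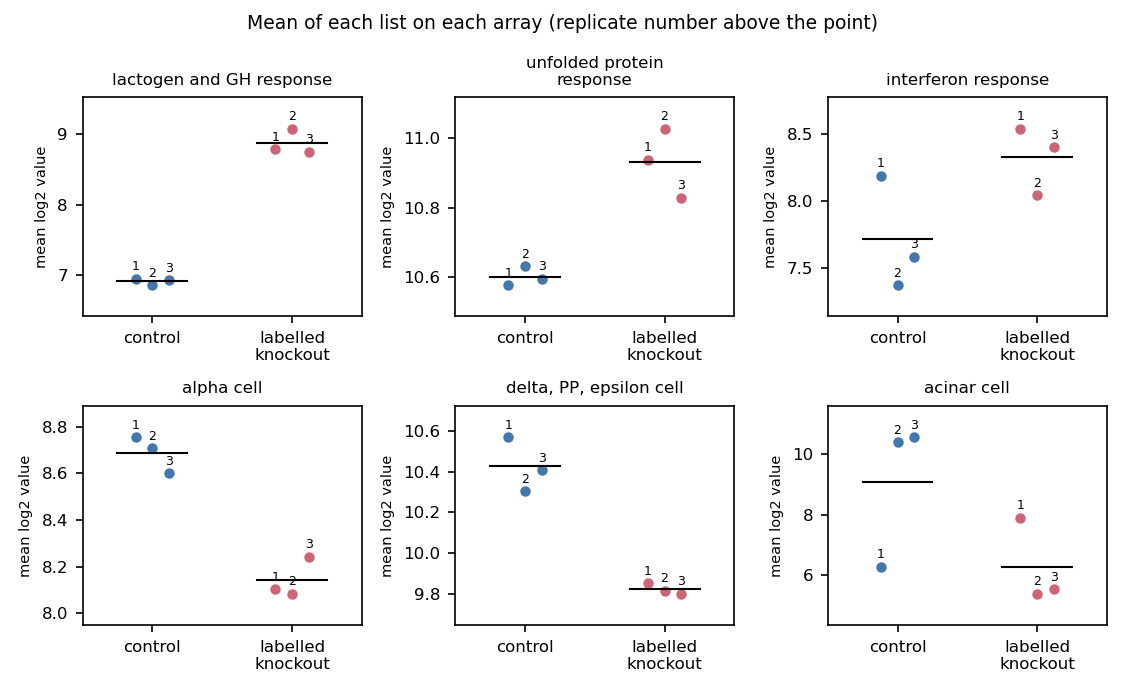
Mean log2 value of 6 gene lists on each array (points, numbered by replicate) with the group mean as a bar. The lactogen and growth hormone list separates the groups (6.92 against 8.87), while acinar markers are high on controls 2 and 3 and low on control 1.

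PPAR target genes did not shift as a list (0.035 ± 0.12, adjusted p = 0.907, and -0.0041 without knockout 3). Of 27 measured, 1 rose and 26 did not pass, and 4 rose and 3 fell when adjusted over the list alone. The gene that rose was Ehhadh, a peroxisomal enzyme of fatty acid oxidation, by 2.07 ± 0.15 (4.2-fold, adjusted p = 0.00289), from 5.67 ± 0.15 to 7.74 ± 0.23. The fatty acid binding protein gene Fabp4 differed by 0.99 ± 0.17 (adjusted p = 0.055) and Fabp3 by -0.91 ± 0.16 (adjusted p = 0.0614), although a second Fabp3 probe set differed by 0.14. The acyl-CoA thioesterase gene Acot2 differed by -0.74 ± 0.13 (adjusted p = 0.0606). The fatty acid oxidation list, which shares 9 genes with the PPAR target list, differed by 0.16 ± 0.09 and did not pass (adjusted p = 0.0688). Ehhadh was its only member past the threshold over all probe sets, and 3 rose when adjusted over the list alone. The mitochondrial carnitine carrier gene Slc25a20 differed by 0.62 ± 0.11 (adjusted p = 0.0651), Acsl4 by 0.55 ± 0.12 (adjusted p = 0.107) and Crot by 0.57 ± 0.16 (adjusted p = 0.2). This list passed without control 1 (0.21, adjusted p = 0.0225), with array weights (0.17, adjusted p = 0.0433) and on the mean over probe sets (0.17, adjusted p = 0.0181). It differed by 0.079 with the acinar covariate (adjusted p = 0.469) and by 0.051 against control 1 alone. The list of PPAR partner receptors and coregulators differed by -0.082 ± 0.068 (adjusted p = 0.115), none of its 14 members passed in either adjustment, and its call was gained without knockout 2 (-0.14, adjusted p = 0.0476). Ppargc1a, a coactivator of mitochondrial genes, differed by -0.50 ± 0.21 (adjusted p = 0.391).

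Genes of hormone release and of the cytoskeleton did not pass as lists with camera. Regulated exocytosis differed by -0.033 ± 0.051 (adjusted p = 0.54, 0.020 after median centring and 0.025 without control 1), and none of 40 members passed over all probe sets or over the list alone. Rab37 (-1.30 ± 0.27, adjusted p = 0.0985), the granin gene Chgb (0.40 ± 0.10, adjusted p = 0.146), Syt4 (0.49 ± 0.15, adjusted p = 0.255) and Scg5 (-0.29 ± 0.10, adjusted p = 0.297) had the smallest p. The actin cytoskeleton list differed by 0.010 ± 0.035 (camera adjusted p = 0.56, fry adjusted p = 0.0418, and -0.014 after quantile normalization again), and none of 61 members passed in either adjustment. Ezr, which links membrane to actin, differed by 0.63 ± 0.14 (adjusted p = 0.109), the severing protein gene Gsn by -0.67 ± 0.15 (adjusted p = 0.122), Zyx by -1.08 ± 0.34 (adjusted p = 0.253) and Actn1 by -0.44 ± 0.15 (adjusted p = 0.283). Among 27 genes of diacylglycerol and protein kinase C or D signalling, Prkd1, a kinase acting at the Golgi, rose by 0.82 ± 0.11 (adjusted p = 0.0311, and on both of its probe sets), and was the only member past the threshold in either adjustment. Its call ended in 5 of the 6 fits that left out 1 array, with an adjusted p of up to 0.14. Plcg2 differed by -0.72 ± 0.24 (adjusted p = 0.273). The mean of this list was 0.025, its median -0.00037 and the direction of its test lower (adjusted p = 0.907).

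Proliferation genes did not pass as a list with camera (-0.092 ± 0.044, adjusted p = 0.144) and passed as lower with fry (adjusted p = 0.0312). None of 39 members passed over all probe sets, and 2 fell when adjusted over the list alone. Cdca8, a chromosomal passenger subunit, differed by -0.91 ± 0.17 (adjusted p = 0.0724) and the cyclin gene Ccna2 by -0.78 ± 0.16 (adjusted p = 0.0912). Birc5 (-0.43 ± 0.17, adjusted p = 0.361) and Mki67 (-0.41 ± 0.17, adjusted p = 0.386) overlapped between groups.

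Among the remaining lists, 65 oxidative phosphorylation genes differed by -0.055 ± 0.018 (adjusted p = 0.131), with Ndufs5 at -0.40 and Cox8a at -0.31. Sterol and fatty acid synthesis differed by 0.033 ± 0.059 (adjusted p = 0.54), with Me1 at 0.59 and Sqle at 0.53, and 2 members rose and 1 fell when adjusted over the list alone. The heat shock list differed by -0.27 ± 0.19 (adjusted p = 0.289), Hspb8 was its only member past the threshold, 3 fell when adjusted over the list alone, and the crystallin gene Cryab differed by -1.70 ± 0.39 (adjusted p = 0.131) with a dim probe set at 0.11. The immediate early list differed by 0.14 ± 0.10 (adjusted p = 0.56), with Jun at 0.51 and Klf2 at 0.57, and passed without control 2 (0.42, adjusted p = 0.00125) and against control 1 alone (0.38, adjusted p = 0.0156). Duct markers differed by -0.14 ± 0.34 (adjusted p = 0.386): Cftr rose, and Clu differed by -0.86 ± 0.18 (adjusted p = 0.101). Without control 1 the duct list passed as lower (-0.42, adjusted p = 6.86e-04), its difference was 0.28 with the acinar covariate (adjusted p = 0.193), and against control 1 alone it passed as higher (0.42, adjusted p = 0.0293). Fibroblast, stellate and smooth muscle markers differed by 0.12 ± 0.07 (adjusted p = 0.341), with Dcn at 0.82 and Mgp at -1.03, and passed without knockout 2 (0.22, adjusted p = 0.0476). Schwann and neuronal markers differed by -0.0091 (adjusted p = 0.331, S100b -0.36 and Tubb3 -0.47) and erythrocyte markers by -0.14 ± 0.08 (adjusted p = 0.248, Hba-a2 -0.34 and Alas2 -0.17). Adipocyte markers had a mean of -0.0013 with a test direction of higher (adjusted p = 0.758), and Pck1 differed by -1.15 ± 0.48 (adjusted p = 0.38). When adjusted over the list alone, 1 rose and 1 fell among duct markers and likewise among fibroblast markers, and 1 adipocyte marker rose. None passed in the oxidative phosphorylation, immediate early, Schwann and erythrocyte lists on the brightest probe set of each gene. A dimmer probe set of the Schwann list member Ngfr rose by 1.14 ± 0.12 (SE, adjusted p = 0.0106, chosen after its values were seen). The sex-linked genes Uty (0.23 ± 0.11) and Xist (-0.22 ± 0.17) did not pass (adjusted p = 0.462 and 0.649), and all 6 arrays had the same pattern, with Eif2s3y (chosen after its values were seen) at a mean of 9.71 in controls and 9.77 in the arrays labelled knockout.

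Control probe sets of the arrays give a measure of handling. The bacterial hybridisation spikes bioB, bioC and bioD averaged 10.69 ± 0.13 in controls and 10.40 ± 0.04 in the arrays labelled knockout, lower on all 3 of the latter (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow). The poly-A spikes averaged 11.50 ± 0.12 and 10.97 ± 0.60, with the low values on knockout 1 and 2. The difference between 3-prime and 5-prime log2 values, a measure of RNA integrity, was 1.88 ± 0.06 and 1.99 ± 0.06 for Gapdh. For beta-actin it was -0.11 ± 0.067 and 0.038 ± 0.017, higher on every array labelled knockout than on every control (exact permutation p = 0.1, two-sided, the smallest possible here). Scan dates were not analysed, so a handling difference that follows the groups cannot be told apart from the genotype.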

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

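The tests of acinar dilution and of cell share in this part were chosen after the results were seen, and the count of other splits was fixed before it was run. Of the 64 control probe sets, which enter no comparison, 3 were above every control array on every array labelled knockout, and 21 were below. Chance separates the groups for 10% of probe sets, both directions together. The 21 that were lower include all 14 probe sets of the bioB, bioC and bioD hybridisation spikes, so the lower side holds the larger departure. Several of these probe sets measure the same spike, so they are not independent and the 10% is a rough guide. Probe sets of the cre hybridisation spike did not separate the groups (-0.0020 to -0.016). The Gapdh 3-prime control probe set was higher by 0.16 on the log2 scale (13.03 ± 0.01 against 13.19 ± 0.03, SD, n = 3). The middle Gapdh control probe set was higher by 0.16 as well, at 11.86 ± 0.02 against 12.03 ± 0.06. The middle probe set of the bacterial trpn control was higher by 0.27, at 3.08 ± 0.05 against 3.35 ± 0.20, which is near the bottom of the range.

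With 6 arrays there are 10 ways to form groups of 3 and 3, so the share of splits with a result as large is never under 0.1 (1 of 10). The real split had 404 probe sets past adjusted p 0.05 and the highest of the others had 0. For an unadjusted p under 0.01 with 1.5-fold change the real split had 1463 and the highest other 560. For gene lists the real split had 11 and the highest other 8. Every other split holds arrays of both groups on each side. Part of the group difference then stays in the contrast, and the rest enters the spread. The counts of the other splits thus do not show what chance alone gives.

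Alpha cell and delta, PP and epsilon cell markers were lower together in the arrays labelled knockout. Acinar RNA could lower islet transcripts by dilution, but controls 2 and 3, with the most acinar RNA, had endocrine marker means at least 0.48 above the highest array labelled knockout, which argues against dilution. The mean differences of both lists lay 0.060 apart, which does not bear on the cause, since shares of alpha and of delta or PP cells need not fall alike. A smaller share of these cells and lower expression within them cannot be told apart on whole islets, and both stay open.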

How the results depend on the processing

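The acinar covariate and the fit without controls 2 and 3 were chosen after seeing the data, and the latter keeps 1 control array, assumed to vary as the arrays labelled knockout do. The difference of Ppard stayed above 0 without passing the threshold in all 15 alternatives. It was 0.31 to 0.63 with 1 array left out, 0.29 with the acinar covariate and 0.22 without controls 2 and 3. The 34 called named genes kept their direction in every alternative that gave a value. Their groups did not overlap, so leaving out arrays could not reverse a direction. Of the 34, 17 stayed past the threshold whichever array was left out, 18 with the acinar covariate and 26 with the replicate block. Signal over background for dim genes is a limit, since RMA values carry no detection call. The cause of a change between settings was not tested.

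Probe sets past adjusted p 0.05 (404) numbered 903 with a trend and robust prior, 725 above the log2 floor, 797 with array weights, 138 with the acinar covariate (114 of them among the 404) and 54 without controls 2 and 3 (44 among the 404). With 1 array left out they ranged from 152 to 783. Probe sets past an unadjusted p of 0.01 and 1.5-fold (1463) numbered 965 above the floor and 1207 to 2475 with 1 array left out. Lists past the threshold (11) fell to 0 of 27 with camera's estimated correlation, where 3 had an unadjusted p under 0.05, and were 8 to 12 in the other alternatives.

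Whether the replicate numbers pair the animals is not settled. Same-numbered arrays deviated from their group means with correlations of -0.054, 0.14 and 0.0045 for replicates 1 to 3. The value of 0.14, for control 2 with knockout 2, was the highest of all pairs, and control 1 with knockout 3 followed at 0.105. Deviations of 3 arrays from their own mean constrain each other, so these values cannot decide it. With the replicate block 246 probe sets passed (210 among the 404) and 11 lists, and 8 of the 34 called named genes did not pass: Kcnh1, Reln, Slc30a8, Prkd1, Pfkp, Gbp6, Ghsr and Rbp4 (adjusted p of 0.0518 for Reln to 0.104 for Slc30a8).

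Golgi and vesicle trafficking (0.10) lost its call after quantile normalization again (0.063), above the floor (0.10), with the acinar covariate (0.068) and without controls 2 and 3 (0.070), and ranged from 0.067 to 0.12 with 1 array left out. Fatty acid oxidation gained a call with array weights (0.17) and on the mean over probe sets (0.17), and ranged from 0.11 to 0.21. Beta cell identity ranged from -0.27 to -0.086 with 1 array left out, regulated exocytosis from -0.080 to 0.025 and PPAR targets from -0.0041 to 0.056. Regulated exocytosis was 0.020 after median centring. Actin cytoskeleton was -0.014 after quantile normalization again and -0.0057 on the mean over probe sets.

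Other lists and genes reversed as follows. Adipocyte markers were 0.020 after quantile normalization again, 0.052 after median centring, 0.029 with either dim filter, 0.021 on the mean over probe sets, 0.019 with the acinar covariate, 0.036 without controls 2 and 3, and -0.065 to 0.049 with 1 array left out. Schwann and neuronal markers were 0.00011 after quantile normalization again, 0.044 after median centring, 0.0019 on the mean over probe sets and -0.11 to 0.085 with 1 array left out. Sterol synthesis was -0.0025 after quantile normalization again, -0.019 with the covariate and -0.051 without controls 2 and 3. PPAR partner receptors were 0.0015 with either filter. Fibroblast markers were -0.070 above the floor, -0.066 with the covariate, -0.15 without controls 2 and 3, and -0.036 to 0.25 with 1 array left out. Diacylglycerol signalling was -0.11 with the covariate, -0.11 without controls 2 and 3 and -0.017 to 0.094 with 1 array left out. Duct markers were 0.28, 0.42 and -0.42 to 0.0096 in the same settings. Endothelial markers were -0.066 with the covariate and -0.13 without controls 2 and 3. The immediate early list ranged from -0.024 to 0.42 with 1 array left out. After median centring Pparg was 0.010 and Ins2 0.0034, and Xist was 0.063 without controls 2 and 3. The acinar list has no value with its own mean as covariate.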

Other observations

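The genes in this paragraph were chosen after their values were seen. They were tested as no group, and genes of the same kinds fell, such as the chemokine gene Ccl27a (-0.94, adjusted p = 0.0397) and the glutamate receptor gene Gria2 (-1.81, adjusted p = 0.00605). In the arrays labelled knockout Il6 rose by 1.61 ± 0.24 (SE, adjusted p = 0.0415), Cxcl11 by 2.40 ± 0.31 (adjusted p = 0.0232), and Csf2rb, the shared beta chain of a cytokine receptor family, by 2.73 ± 0.42 (adjusted p = 0.0436). Cxcl5 went from 4.42 ± 0.53 to 6.42 ± 0.41 (SD, n = 3 arrays, adjusted p = 0.0439). The adhesion molecule gene Icam1 rose by 1.11 ± 0.14 (adjusted p = 0.0232). Gfra3, a co-receptor for a neurotrophic factor, went from 6.65 ± 0.18 to 9.93 ± 0.09 (SD, n = 3), and Acvr1c, a type I receptor of the activin family, from 6.52 ± 0.20 to 9.63 ± 0.19. Igfals, a liver gene induced by growth hormone that encodes a carrier of IGFs, rose by 1.54 ± 0.20 (adjusted p = 0.0228). Igf2 fell by 0.96 (SE 0.13, adjusted p = 0.0289), Cbs, which makes cystathionine, fell by 1.32 (SE 0.12, adjusted p = 0.00668), and Itpr3, a calcium release channel gene, fell by 1.06 (SE 0.12, adjusted p = 0.0118).

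The tests in this and the next paragraph were chosen after the results were seen. Tph1, Socs2, Cish, Matn2 and Ehhadh rose together. Acinar RNA is argued against as the whole cause, since the list mean still differed by 1.89 with the acinar covariate (adjusted p = 8.8e-13 with camera's preset correlation, against an adjusted p = 0.108 with an estimated correlation and no covariate). Signalling through a growth hormone or lactogen receptor stays open as a hypothesis: the list lay at percentile 100 of 10000 random lists of its size and expression level, which restates the rise and does not bear on its cause. There were 0 arrays from Cre-positive mice with intact Ppard alleles, so the Cre transgene and the deletion cannot be told apart as its origin. Some Cre transgenes carry growth hormone sequence, and whether this one does is not given in the sources used here.

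Called genes lay next to each other more often than shuffled calls. Of 198 called genes with a position, 21 had a neighbouring measured gene called in the same direction, against at most 16 in 10000 shuffles within expression bins (permutation p = 1e-04, the smallest these shuffles can give). Examples are Cftr with Cttnbp2 (3.92 and 1.58), Gdf3 with Apobec1 (3.99 and 1.14) and Socs2 with Cradd (2.09 and 1.04). Names counted as related where their opening letters matched. A clone name beside a gene name cannot match, so pairs such as Socs2 with 5730420D15Rik stayed in. Without neighbours of related name 17 genes remained (permutation p = 1e-04, also the smallest). That argues against cross-hybridisation within families of shared name as the whole cause. The pairs lay on 9 chromosomes, which argues against a single passenger segment beside the transgene as the source of all of them. Shuffled calls alone gave 2.96 such genes on average, so a segment that holds some of the pairs is not excluded. Shared regulatory regions may account for the pairs, as a hypothesis that was not tested, and shuffles do not keep any regional expression that exists without the deletion. The animals were on a mixed strain background, and the strain origin of these regions was not analysed.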
